A study of Sus scrofa with 36 samples.

How the data were processed

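Bulk RNA-seq was measured in 36 libraries in 11 groups. Per the labels, RNA was purified with the QIAGEN RNeasy Plus Mini kit and libraries were made by ligation-mediated sequencing (LM-seq). Whether the kit and the counting kept the strand was not given in the sources used here, so reads of overlapping or antisense genes may be shared. Reads of near-identical copies (paralogs, pseudogenes, multigene families such as the LOC genes of chromosome Y) may be shared as well, and their values are uncertain. Per the submitters' processing notes the tools were bcl2fastq, Bowtie 1.2.3 and RSEM 1.2.3 with the genome build Sscrofa11.1. The authors deposited a table of expected counts per gene and library, the numbers of reads that RSEM assigns to a gene, in part by estimation. The authors also deposited a table of TPM, in which counts are divided by effective gene length and scaled to the same total in every library. Each table held 20683 genes, of which 2097 were at 0 in every library, and all 36 columns of each were used. Gene symbols matched RefSeq for 20618 genes, and coordinates are those of RefSeq genes on Sscrofa11.1. TBXT stands in the table under its older symbol T.

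Groups and replicate numbers were taken from the labels. None of the 42 pairs of libraries of a group was identical, so each library counted as 1 replicate. The lowest chi-square per degree of freedom was 3.53. Clone 3 replicates 2 and 3 had 4.998 against 44.6 to 66.8 for other clone 3 pairs. They may not be independent, which would understate clone 3's spread. Low genes are measured less precisely in clone 8. With 3 libraries against 3 neither a test on ranks nor other splits can reach a share under 0.05, and the gene tests rest on a spread shared across genes.

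Expected counts were rounded to whole numbers, which moved values by 0.00094896% on average. They were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, after TMM scaling and a filter with filterByExpr (minimum count 10). Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene passed at an adjusted p under 0.05 with no minimum fold change. The SE of a log2 fold change was the size of the change divided by the square root of the F statistic. One model per set was fitted, over 15 libraries and 14660 genes for fibroblasts and clones 1 to 3 and over 21 libraries and 14248 genes for clone 8. Clones against fibroblasts used the mean of the 3 clones, and a lineage against the others used the mean of the other two. TPM values are means and SDs over libraries and entered no main test. Genes at 0 in all libraries of a group have no fold change, and TPM is given. In list medians such a group was also set to a floor of 3 counts over the group, which covers counting error only.

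The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Of 32 lists 31 had tested members, and fry of limma 3.58.1 was run on each, adjusted by Benjamini-Hochberg over the lists of a comparison. Named were fixed marker genes. Per list, up to 3 members with the largest change in the commoner direction and the 1 changed most the other way were named. The 5 highest and 5 lowest genes with a symbol, at least 10 TPM in the higher group and no overlap of the libraries were named too. For the lineage comparisons the text names only part of the genes that the rule gives, a restriction made after their values under the alternatives had been seen. Genes beyond the rule were chosen after their values were seen, among them list members named beside a small count. Values of some genes that the rule gives are not reported here, and the counts include these genes. Members of lists not analysed here were COL6A1, H19, MEG3, KRT7, PAX8, HOXB4, HOXB9, HOXD4, CYP26B1, MYH6, MYH3, MYH8, TUBB3 and ELAVL4, and the list of mitochondrial genes as a whole.

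Alternatives were DESeq2 1.42.0 (Wald test), RLE scaling, no filter, a minimum fold change of 2, other choices of libraries in the fit, the replicate number as a block, limma on log2(TPM + 1) and on log2(TPM + 0.1), counts summed per clone, and leaving out each library. Chosen after the data were seen were the fits without cardiomyocyte replicate 2 and neural progenitor replicate 1, those with fibroblast libraries 1 and 2 or 3 and 4 alone, and fry over only the groups compared. The tests were tried on simulated counts drawn from the means and library sizes of each comparison, with 50 genes changed by each of 4 fold sizes. For clones against fibroblasts (14660 genes) edgeR recovered 88% of genes changed 8-fold, 68% at 4-fold, 44% at 2-fold and 2% at 1.5-fold, with 3 false calls. For day 1 against day 0 (14248 genes) the shares were 78%, 50%, 4% and 0%. Over the 16 simulated comparisons false calls numbered 56 by edgeR, 83 by limma and 511 by DESeq2. These simulations were first run after the models had been fitted to the deposited counts.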

Results

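Bulk RNA-seq was collected from 36 libraries of pig (Sus scrofa) cells in 11 groups. They comprised fibroblasts, induced pluripotent stem cells (iPSCs) that the study's title calls transgene-free, and cells differentiated from them. A first set of 15 libraries held fibroblasts (n = 4) and 3 undifferentiated clonal iPSC lines, clone 1 (n = 3), clone 2 (n = 4) and clone 3 (n = 4). A second set of 21 libraries followed a further line, clone 8, with 3 libraries per group. Undifferentiated cells from which the feeder layer had been removed were taken on day 0. Cells on the way to somites, the blocks of mesoderm that form trunk muscle and bone, were taken on day 1 (mesendoderm), day 2 (presomitic mesoderm, PSM) and day 3 (somite). Cells of other lineages were labelled endothelial on day 6, beating cardiomyocyte on day 9 and neural progenitor on day 24. Total estimated counts ran from 1845333 to 69879325 per library. Clones 1 to 3 had at least 24314241 counts. The libraries of clone 8 had at most 9727315. Among the fibroblasts, libraries 1 and 2 had 36738189 and 26120236 counts and libraries 3 and 4 had 7508792 and 6877298. No label said whether libraries of a group came from separate cultures, so the p-values measure the spread between libraries, which may be technical. Levels are in TPM (mean ± SD over the libraries of a group), and fold changes are log2 values ± SE. Adjusted p-values of genes come from the edgeR quasi-likelihood test. For each gene list the number of members past that test over all genes is followed by the number when adjusted over the list alone (written "alone"). The false discovery rate (FDR) given for a list is the adjusted directional p of fry, which asks whether its genes move on balance one way. Fry's mixed p asks whether they change in either direction, and neither compares the list with other genes. Where a member was at 0 in every library of a group, a list's median is also given with such members at the bound set by 3 counts over that group ("at the floor").

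To ask how far the clones had left the fibroblast state, clones 1 to 3 (11 libraries, equal weight per clone) were compared with fibroblasts (n = 4). The transcription factor genes at the centre of the pluripotency network were abundant in the clones and close to the limit of detection in fibroblasts. POU5F1, which encodes OCT4, stood at 851 ± 126 against 0.407 ± 0.432 TPM (log2 fold change 11.07 ± 0.3, adjusted p = 2.78e-15). It lies on chromosome 7 of Sscrofa11.1 (23564654 to 23570691). NANOG stood at 101 ± 18.3 against 0.158 ± 0.182 TPM (10.69 ± 0.43). SOX2 (chromosome 13, 119668476 to 119669435) stood at 112 ± 19.8 against 0.365 ± 0.73 TPM (7.66 ± 0.52). LIN28A, an RNA-binding protein that blocks the maturation of let-7 microRNAs, reached 1198 ± 264 TPM against 1.33 ± 1.41. All 15 tested members of the pluripotency list were higher (alone 15, FDR = 2.87e-11), with a median of 9.56 (7.8 at the floor). TDGF1, a co-receptor for nodal, and TERT, the catalytic subunit of telomerase, were at 18.8 ± 6.22 and 2.37 ± 1.02 TPM in the clones and at 0 in all 4 fibroblast libraries. Epithelial genes took the same direction, with 16 of 16 higher (alone 16, FDR = 8.66e-13). CDH1, the gene of E-cadherin (chromosome 6, 18075487 to 18155986), stood at 1431 ± 230.4 against 0.535 ± 0.345 TPM. EPCAM stood at 801 ± 66.8 against 0.603 ± 0.487 and GRHL2 at 25.4 ± 4.47 against 0.01 ± 0.02. Fibroblast and mesenchyme genes were lower in 24 of 24 cases (alone 24, FDR = 3.17e-12; median -7.25). COL1A1, a chain of type I collagen (chromosome 12, 26379087 to 26397180), stood at 156 ± 54 against 9634 ± 1091 TPM (-6.09 ± 0.13). THY1 stood at 5.4 ± 1.88 against 399.8 ± 261 TPM (-6.02 ± 0.29) and the intermediate filament gene VIM at 349 ± 83.2 against 3211 ± 293 (-3.33 ± 0.11). The proteoglycan genes DCN (-10.52 ± 0.34) and LUM (-10.51 ± 0.27) and the receptor gene PDGFRB (0.396 ± 0.391 against 130.4 ± 27.2 TPM) were lower still.

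Genes often used to tell naive from primed pluripotency did not move as blocks. Of 11 naive-associated genes, 5 were higher in the clones (PRDM14, DPPA3, FGF4, TFAP2C and ESRRB) and 6 lower (KLF2, KLF4, TFCP2L1, NR5A2, TBX3 and KLF5), alone 5 and 6. For this list fry's direction was up (FDR = 1.04e-05), with a mean of 1.8 and a median of -0.86. PRDM14 stood at 47.2 ± 12.3 TPM against 0. KLF4, one of the classical reprogramming factors (chromosome 1, 248604817 to 248609574), stood at 3.54 ± 1.6 against 97.1 ± 14.6 TPM (-4.96 ± 0.28). KLF2 stood at 0.0727 ± 0.108 against 1.96 ± 1.23 TPM and TFCP2L1 at 0.243 ± 0.28 against 3.59 ± 0.63 (-4.21 ± 0.76). Of 11 primed-associated genes, 8 were higher and 3 lower (alone 8 and 3, FDR = 3.28e-11, up). ZIC2 (10.83 ± 0.47) and SOX11 (10.7 ± 0.38) were among the higher. FGF5, at 0.0373 ± 0.0671 against 14.9 ± 3.71 TPM, was among the lower. Cell cycle genes were higher in 17 of 17 cases (alone 17, FDR = 8.66e-13). BIRC5, which encodes survivin, stood at 348 ± 103 against 2.65 ± 2.06 TPM, and TOP2A (6.18 ± 0.41) and CCNB2 (5.73 ± 0.32) followed. Glycolysis genes were lower in 12 of 13 cases and higher in 1 (alone 12 and 1, FDR = 9.43e-09, down). HK2 (-4.19 ± 0.14), LDHA (581 ± 243 against 3409 ± 89.9 TPM) and the glucose transporter gene SLC2A1 (-2.64 ± 0.16) were lower. The transporter gene SLC2A3 was higher, at 1828 ± 389 against 203 ± 113 TPM. Imprinted genes split into 6 higher and 5 lower of 14 (alone 6 and 5). Fry's direction was down (FDR = 0.000172), with a mean of 0.46 and a median of 0.53. DLK1 was at 7.69 ± 2.41 TPM against 0, NNAT at 37.5 ± 7.97 against 5.49 ± 0.909 and NDN at 30.6 ± 27.4 against 1.02 ± 1.25. NDN was lower than in fibroblasts in clone 3 (0.25 ± 0.13 TPM). SGCE was at 3.91 ± 0.938 against 193 ± 12.1. Stress and immediate early genes were lower in 7 of 12 cases and higher in 2 (alone 7 and 2, FDR = 9.43e-09, down). DDIT3 (-5.15 ± 0.42), FOSB (0.0973 ± 0.0952 against 0.685 ± 0.466 TPM) and JUNB (-3.91 ± 0.31) were lower and IER2 (1.04 ± 0.19) higher. Among the genes with the widest differences at 10 TPM or more, CYP26A1, a retinoic acid-degrading enzyme, stood at 117 ± 86.3 TPM against 0. NPM2 stood at 102 ± 22.6 against 0 and the cationic amino acid transporter gene SLC7A3 at 61.9 ± 14.1 against 0. EIF1AY stood at 85.5 ± 13.7 TPM against 0. It lies on chromosome Y (9687350 to 9704489), where 8 genes of one stretch were counted in clones 1 to 3 and barely in the other 25 libraries. At the other end stood ELN, the elastin gene (0.0845 ± 0.0513 against 929.5 ± 322 TPM), THBS2 (0.106 ± 0.0401 against 665 ± 62.3) and ASPN (0.0355 ± 0.0416 against 339.5 ± 103). PRELP (0.0164 ± 0.0129 against 113 ± 56.4) and ZBED2 (0.00182 ± 0.00603 against 70.1 ± 20.4) lay there too.

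In the test across all genes, 10930 of 14660 passed at an adjusted p under 0.05, 5666 higher and 5264 lower in the clones, and 8476 changed at least 2-fold. Scaling left the median of all genes at 0.11, and fold changes are relative to that shift. Each clone against the same fibroblasts gave 10186 genes for clone 1 (5293 higher, 4893 lower), 10246 for clone 2 (5534 and 4712) and 10355 for clone 3 (5534 and 4821). The medians of all genes were 0.033, 0.17 and 0.15. POU5F1 differed by 11.32 ± 0.31, 10.77 ± 0.3 and 11.13 ± 0.31 in clones 1, 2 and 3, and COL1A1 by -5.72 ± 0.22, -5.88 ± 0.19 and -6.68 ± 0.2. The fibroblast libraries formed 2 batches by depth and by the effective gene lengths implied by the deposited values. Against libraries 1 and 2 alone 10922 genes passed and against libraries 3 and 4 alone 9861. The same counts were 10467 and 9407 for clone 1, 10410 and 9163 for clone 2 and 10533 and 9349 for clone 3. All 104 results for named genes kept their call in both batches.

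**Figure D1:**
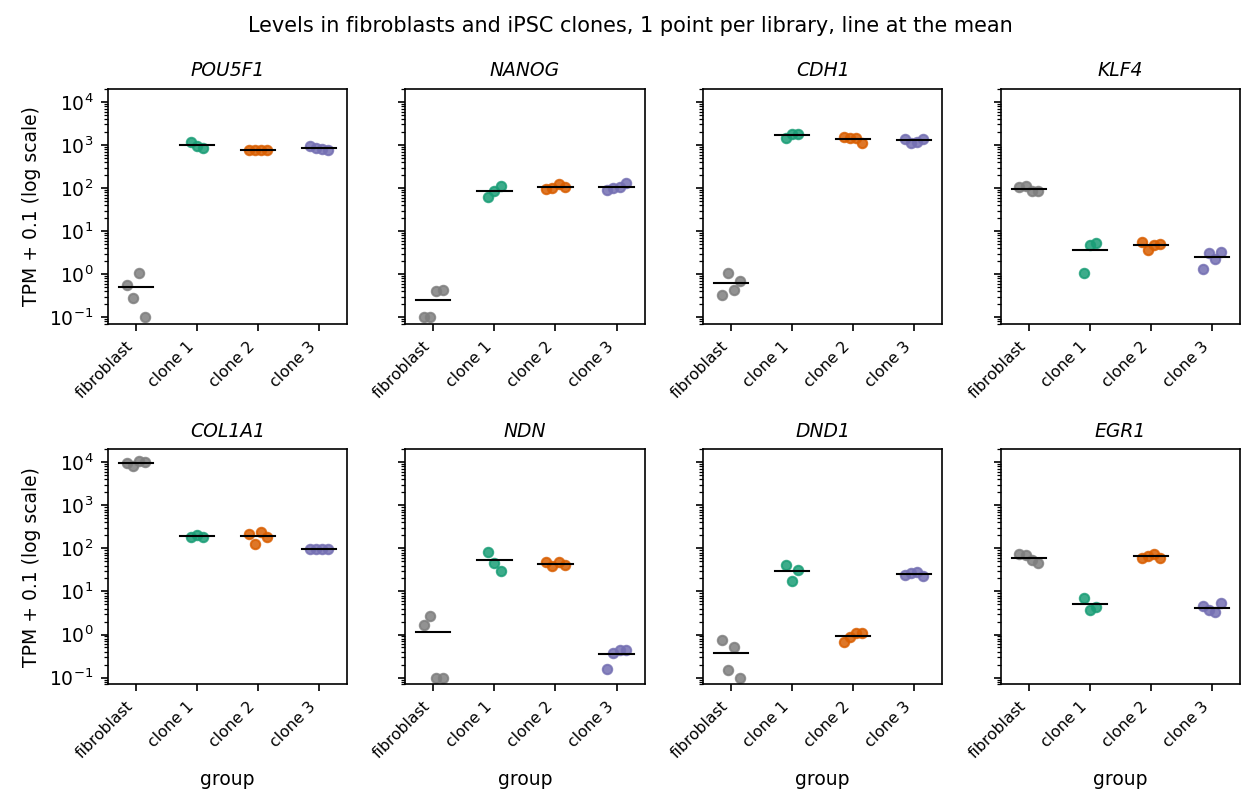
TPM + 0.1 on a log axis for 8 genes in fibroblasts (n = 4) and clones 1 to 3 (n = 3, 4 and 4); points are libraries and lines are means. POU5F1, NANOG and CDH1 are high in each clone, KLF4 and COL1A1 are high in fibroblasts, and NDN, DND1 and EGR1 separate 1 clone from the others, as with DND1 at 0.84 ± 0.213 TPM in clone 2 and 30 ± 12.3 in clone 1.

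To see whether the clones differ, they were compared in pairs, without separating clone from derivation or culture. Across genes (Spearman, log2 CPM), clone 1 replicate 4 correlated more with clone 2 (0.9721) than with clone 1 (at most 0.9641) and clone 1 replicate 2 about as much with clone 3 (0.9598) as with clone 1 (0.9595). Clone 1 and clone 2 had levels of the core pluripotency genes that the test did not separate. POU5F1 stood at 979.9 ± 175 against 759 ± 11.4 TPM (adjusted p = 0.0716) and NANOG at 87.1 ± 24.1 against 107 ± 12.4 (0.753). SOX2 stood at 118 ± 19.6 against 122 ± 19 TPM (0.858) and LIN28A at 861 ± 299 against 1324 ± 113 (0.355). CDH1 (0.45, adjusted p = 0.29), KLF4 (-0.19, 0.809), COL1A1 (0.17, 0.583) and THY1 (0.29, 0.706) did not pass either. Endoderm-associated genes were lower in clone 1 in 6 of 11 cases (alone 8, FDR = 5.42e-05). The apolipoprotein gene APOA1 stood at 209 ± 45.7 against 741 ± 29.1 TPM, FOXA1 at 0.677 ± 0.14 against 3.71 ± 0.635 and HNF4A at 0.0233 ± 0.0252 against 1.08 ± 0.357. Primitive streak genes were lower in 3 of 11 cases (alone 4 lower and 1 higher, FDR = 0.00136). CER1, a nodal and BMP antagonist, stood at 63.1 ± 9.34 against 158 ± 15.1 TPM, TBXT at 8.46 ± 4.05 against 21.8 ± 4.31 and MESP1 at 0 against 0.15 ± 0.0845. Stress genes were lower in 3 of 12 cases (alone 3 lower and 1 higher, FDR = 0.000374; mean -1.01, median 0.0055), all of them growth factor-induced genes. EGR1 stood at 4.92 ± 1.67 against 65.3 ± 6.93 TPM (-3.55 ± 0.28, adjusted p = 2.23e-06), FOS at 3.54 ± 3.5 against 25.3 ± 5.28 and FOSB at 0 against 0.17 ± 0.104. Higher in clone 1 was DND1, a germ cell RNA-binding protein, at 30 ± 12.3 against 0.84 ± 0.213 TPM (5.34 ± 0.46). SHISA2 stood at 56.9 ± 3.24 against 0.46 ± 0.482 and FAM83F at 15.2 ± 3.91 against 0.04 ± 0.0337. LEFTY2, a nodal inhibitor, stood at 176 ± 49.3 against 23.4 ± 5.89 TPM, the imprinted gene PEG3 at 2.43 ± 0.352 against 0.0075 ± 0.005 and KRT79 was higher by 2.42 ± 0.32. Lower were BAALC (-5.29 ± 1.19), LURAP1L (-4.03 ± 0.7) and the Wnt antagonist DKK1 (-2.54 ± 0.69). TDGF1 (-1.02 ± 0.27) was the lower pluripotency gene of 15 (alone 1, FDR = 0.927, down, mean 0.043). TFAP2C (1.27 ± 0.27) was the higher naive-associated gene of 11 (alone 1 higher and 1 lower, FDR = 0.255). OTX2 (-1.54 ± 0.27) was among the 2 lower primed-associated genes of 11 (alone 2 lower and 1 higher, FDR = 0.0709). TFAP2A (-1.94 ± 0.58) was the lower trophectoderm gene of 7 (alone 1, FDR = 0.523). Fibroblast genes gave 1 higher, VIM (0.83 ± 0.16), and 4 lower of 24, among them PDGFRB, SNAI2 and TWIST1 (alone 2 and 4, FDR = 0.0754). PEG3 was the higher imprinted gene of 14 (alone 1, FDR = 0.917, up, median -0.12, mean 0.18). Of 17 cell cycle genes 0 passed by edgeR, also alone. At an unadjusted p under 0.05 there was 1, and by DESeq2 and limma there were 0 (FDR = 0.917, down, median 0.031, mean -0.023). Over all genes 1365 passed, 655 higher and 710 lower in clone 1, of which 754 differed at least 2-fold. The count was 643 without clone 2 replicate 3.

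Among genes at 10 TPM or more, the widest differences between clone 1 and clone 3 were in genes low in clone 3. NDN, an imprinted gene of the Prader-Willi region in humans, stood at 52.8 ± 27.6 against 0.25 ± 0.13 TPM (7.69 ± 0.65, adjusted p = 4.29e-06). It lies on chromosome 1, 142412688 to 142413665. TCEAL2 stood at 45.3 ± 7.26 against 0.278 ± 0.459 TPM, GRHPR, a glyoxylate reductase gene, at 25.7 ± 6.3 against 1.13 ± 0.657 and the amylase gene AMY2 at 98.8 ± 2.37 against 4.42 ± 0.897. SHISA2 stood at 56.9 ± 3.24 against 1.3 ± 0.359. NDN and PEG3 (8.83 ± 0.94) were the higher imprinted genes of 14 (alone 2, FDR = 0.103, up, median -0.027, mean 0.85). DNMT3B, a de novo DNA methyltransferase gene, was lower in clone 1, at 1132 ± 74.4 against 2349 ± 244 TPM (-1.06 ± 0.16). It lies on chromosome 17 (36345715 to 36386076), as do PCNA and HNF4A, and the tested genes of that chromosome had a median log2 difference of 0.53 between clone 3 and the other clones. DNMT3B and TDGF1 (-1.18 ± 0.27) were the lower and LIN28B (0.89 ± 0.18) the higher pluripotency genes (alone 2 and 1, FDR = 0.139). POU5F1 (979.9 ± 175 against 845 ± 70.4 TPM, adjusted p = 0.582), NANOG (0.559), SOX2 (0.701) and LIN28A (0.198) did not pass, nor did KLF4 (0.408), CDH1 (0.394) and THY1 (0.884). FN1 (1.0 ± 0.21), COL1A1 (0.96 ± 0.17), COL5A1 (0.84 ± 0.16) and VIM (0.58 ± 0.16) were higher in clone 1. They were 4 of 24 fibroblast genes, and 3 were lower (alone 5 and 5, FDR = 0.2). CER1 (-1.39 ± 0.19) and HNF4A (-4.14 ± 1.02) were the lower endoderm genes of 11 (alone 2, FDR = 0.0748). CER1 was also the lower streak gene of 11 (alone 3, FDR = 0.103). OTX2 (-0.89 ± 0.26) was the lower primed-associated gene of 11 (alone 4, FDR = 0.101) and TFAP2A (-2.46 ± 0.58) the lower trophectoderm gene of 7 (alone 1, FDR = 0.753). PCNA, the sliding clamp of DNA replication, was the lower cell cycle gene of 17 (-1.09 ± 0.22; alone 1, FDR = 0.369). FOSB was the lower stress gene of 12 (alone 1, FDR = 0.215, up, median 0.32, mean -0.22). Of 11 naive-associated genes 0 passed by edgeR, also alone. There were 2 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma (FDR = 0.437). Lower by the widest margin at 10 TPM or more were TIMM9 (-1.68 ± 0.37), BLOC1S5 (-1.56 ± 0.44), NUP54 (-1.5 ± 0.2) and NRARP (-1.36 ± 0.38). In all, 982 genes passed, 457 higher and 525 lower in clone 1, of which 563 differed at least 2-fold. Without clone 3 replicate 3 the count was 435.

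Clone 2 and clone 3 differed in NDN as well, at 44.2 ± 5.26 against 0.25 ± 0.13 TPM (7.24 ± 0.64), in TCEAL2 at 47.4 ± 21.9 against 0.278 ± 0.459 and in GRHPR at 29.4 ± 2.1 against 1.13 ± 0.657. AGPAT3 stood at 14.3 ± 2.79 against 0.652 ± 0.318 TPM and SLC3A1, an amino acid transporter subunit gene, at 10.3 ± 1.6 against 0.552 ± 0.419. EGR1 (65.3 ± 6.93 against 4.11 ± 0.867 TPM, 3.81 ± 0.26, adjusted p = 9.69e-08) and FOS (25.3 ± 5.28 against 1.91 ± 0.513 TPM) were higher in clone 2. They were the stress genes of 12 to pass (alone 3, FDR = 5.49e-05). Endoderm genes were higher in clone 2 in 3 of 11 cases (alone 4, FDR = 0.00107). These were FOXA1 (2.54 ± 0.38), APOA1 (1.62 ± 0.36) and SOX17 (1.22 ± 0.24). DND1 was lower in clone 2, at 0.84 ± 0.213 against 25.4 ± 2.41 TPM (-5.1 ± 0.44). So were the meiotic gene RBM46 (-3.93 ± 0.37), DOK5 (-2.28 ± 0.3), MYCN (-1.94 ± 0.25) and ASS1 (-1.73 ± 0.17). DNMT3B (1304 ± 100 against 2349 ± 244 TPM, -1.03 ± 0.14) was the lower pluripotency gene of 15 (alone 1, FDR = 0.0669). PCNA (-0.92 ± 0.2) was the lower cell cycle gene of 17 (alone 1, FDR = 0.477). Both lie on chromosome 17, as do DOK5 and TFAP2C. POU5F1 (759 ± 11.4 against 845 ± 70.4 TPM, adjusted p = 0.312), NANOG (0.882), SOX2 (0.911) and LIN28A (0.83) did not pass, nor did KLF4 (0.284), CDH1 (0.951), VIM (0.441) and THY1 (0.905). PRDM14 (0.65 ± 0.14) and TFAP2C (-1.19 ± 0.26) took opposite sides among 11 naive-associated genes (alone 1 higher and 1 lower, FDR = 0.644). SOX11 (-0.82 ± 0.19) was lower among 11 primed-associated genes (alone 3 higher and 2 lower, FDR = 0.754). Fibroblast genes gave 4 higher, among them FN1 (1.26 ± 0.2), COL1A1 (0.8 ± 0.16) and PDGFRA (1.36 ± 0.35), and 1 lower of 24, COL3A1 (-0.95 ± 0.23). Alone these were 5 and 1 (FDR = 0.643, up, median -0.071, mean -0.0099). NDN was the higher imprinted gene of 14 (alone 1, FDR = 0.0389, up). By edgeR 0 of 11 streak genes passed, also alone (2 at an unadjusted p under 0.05, 2 by DESeq2 and 3 by limma, FDR = 0.0636). Of 7 trophectoderm genes 0 passed too (2, 1 and 1 in the same order, FDR = 0.754). Altogether 618 genes passed, 302 higher and 316 lower in clone 2, of which 280 differed at least 2-fold. Without clone 2 replicate 3 there were 330, and with only these clones fitted 2561.

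**Figure D2:**
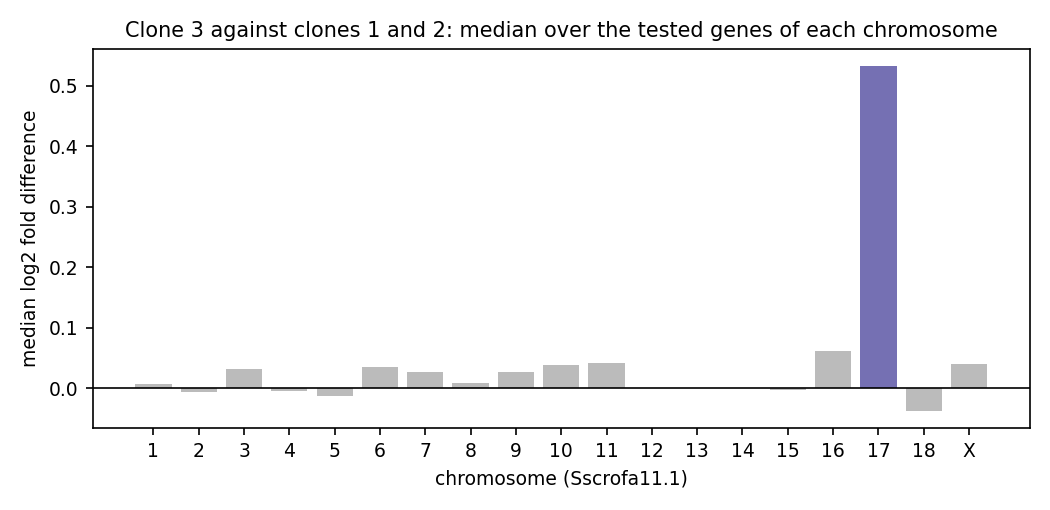
Median log2 fold difference between clone 3 and the mean of clones 1 and 2 over the tested genes of each chromosome, 1 bar per chromosome, from TMM-scaled counts. The bar of chromosome 17 stands at 0.53 (445 genes), and the other 18 lie between -0.037 and 0.062.

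**Figure D3:**
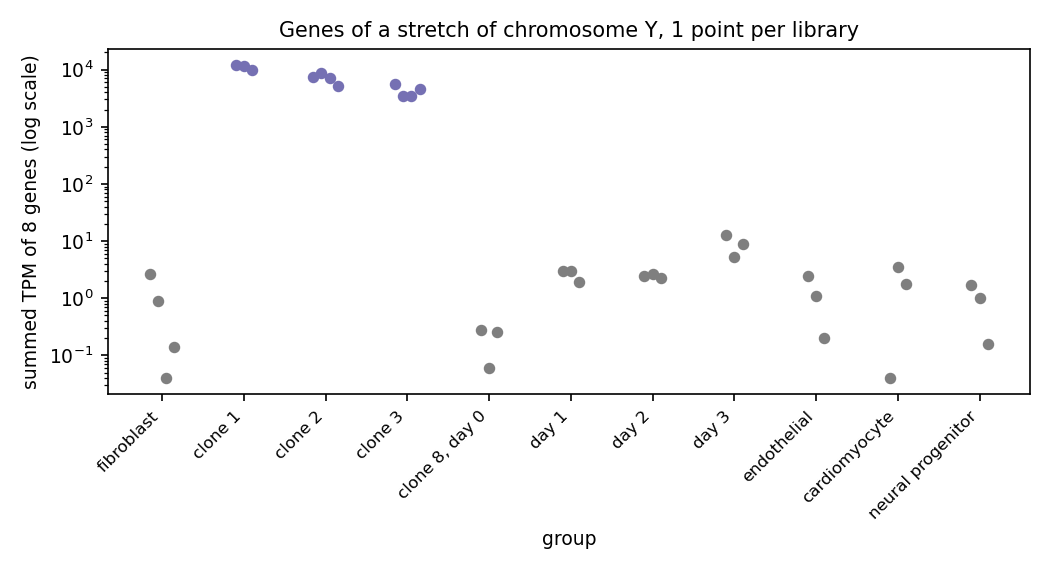
Summed TPM, on a log axis, of 8 genes of chromosome Y between 9155794 and 10444524, 1 point per library for the 11 groups. The libraries of clones 1 to 3 lie between 3493 and 12091, and the highest of the other libraries, at day 3, is at 12.9.

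The time course of clone 8 was set up to follow the steps from pluripotent cells through primitive streak and PSM to somite. The spread was estimated over all 21 libraries of clone 8, and a pair of them, labelled cardiomyocyte replicate 2 and neural progenitor replicate 1, sat with another group than their own. From day 0 to day 1, genes of the primitive streak, the site where mesoderm and endoderm leave the epiblast, rose in 11 of 12 cases (alone 11, FDR = 5.89e-11). TBXT, which encodes brachyury, rose to 307 ± 97.7 from 10.3 ± 1.92 TPM (5.1 ± 0.43, adjusted p = 1.22e-06). It lies on chromosome 1, 2717165 to 2725561. MIXL1 (chromosome 10, 14102273 to 14105544) rose to 149 ± 40.6 from 0.18 ± 0.18 TPM, and EVX1 (6.23 ± 1.0) and MESP1 (5.37 ± 0.95) rose with it. Wnt target genes rose in 7 of 11 cases and TNFRSF19 (-1.43 ± 0.22) fell (alone 7 and 1, FDR = 1.01e-05). DKK1 reached 824 ± 128 TPM from 15.1 ± 3.46, LEF1 50.5 ± 22.7 from 1.6 ± 0.764 and NKD1 48.4 ± 13 from 2.07 ± 0.57. Of 14 presomitic genes 8 rose and HES4 fell (alone 11 and 1, FDR = 1.94e-06). RSPO3, a Wnt agonist, reached 201 ± 66 TPM from 7.44 ± 3.25 and CDX1 1.86 ± 0.915 from 0. MSGN1 (chromosome 3, 120033980 to 120034624) reached 12.2 ± 5.18 TPM from 0. TBX6 (chromosome 3, 18271983 to 18277864) reached 5.79 ± 3.99 TPM from 0.987 ± 0.723. Nodal pathway genes rose in 4 of 8 cases (alone 4, FDR = 0.0002), with CER1 at 193 ± 3.52 TPM, NODAL higher by 5.96 ± 0.97 and SKIL by 1.97 ± 0.51. Pluripotency genes parted, with 2 of 15 higher and 3 lower (alone 2 and 3, FDR = 0.0954, and 6.17e-07, down, without the pair). SOX2 fell to 2.37 ± 1.76 from 174 ± 2.81 TPM (-5.99 ± 1.52), NANOG to 8.74 ± 0.816 from 68.8 ± 0.43 and DNMT3B to 115 ± 34.2 from 1601 ± 109. POU5F1 stood at 616 ± 37.6 and 717 ± 69.9 TPM and did not pass. Epithelial genes fell in 8 of 16 cases (alone 8, FDR = 0.000215), among them the claudin genes CLDN3 (-5.2 ± 0.61) and CLDN4 (-4.94 ± 0.86) and GRHL2 (-2.97 ± 0.42). Stress genes fell in 5 of 12 cases (alone 5, with 1 higher, FDR = 0.00245), led by EGR1 (-5.14 ± 0.88) and ATF3 (-4.72 ± 0.99). Of 11 FGF-ERK targets EGR1 and ETV5 (-0.96 ± 0.26) fell (alone 5, with 1 higher, FDR = 0.00557).

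Genes of other layers were also counted on day 1. GATA6 (5.63 ± 1.7), SOX17 (152 ± 51.3 against 21.4 ± 7.81 TPM) and CER1 rose and FOXA1 (-3.36 ± 0.35) fell among 11 endoderm genes (alone 5 and 1, FDR = 0.0102, up). HAND1 (6.85 ± 1.6) and CDX2 (3.24 ± 0.7) rose among 7 trophectoderm genes (alone 2, FDR = 0.00782). PDGFRA (79.3 ± 14.2 against 1.46 ± 0.185 TPM), DPT and TWIST2 (1.85 ± 0.56) rose among 23 fibroblast genes (alone 3, FDR = 0.495, and 0.00363 without the pair). The segmentation clock list shares DKK1, NKD1 and AXIN2 (3.19 ± 0.72) with the Wnt targets. It had 5 of 15 members higher and 2 lower (alone 7 and 4, FDR = 0.000313, up). Of 26 HOX genes 4 rose, all to low levels, as HOXB6 to 1.19 ± 0.124 TPM from 0 (alone 4, FDR = 0.000101). Of 10 BMP targets MSX1 (4.87 ± 0.9) rose and ID4 (-2.67 ± 0.65) fell (alone 3 and 1, FDR = 0.248, and 8.86e-05, up, without the pair). HES7 (chromosome 12, 53334350 to 53339336) stood at 0.91 ± 0.704 TPM (adjusted p = 0.111), and MEOX1 (0.157 ± 0.15, 0.864) and FOXC2 (0.0633 ± 0.11, 0.214) did not pass either. Without the pair HES7 was higher (adjusted p = 0.0171) and FOXC2 lower (0.0146). TCF15 (chromosome 17, 34626682 to 34632881) fell by 1.84 ± 0.49 on the log2 scale to 2.52 ± 1.08 TPM. The widest differences at 10 TPM or more were KLHL6 (9.15 ± 0.72) and DKK4 (7.17 ± 1.15) upwards. VGLL1 (0 against 14.7 ± 4.01 TPM), CD1D, THSD1, FOXD3 (-7.62 ± 1.29) and DGKB (-7.15 ± 1.61) went down. Of 17 cell cycle genes 0 passed by edgeR, also alone, with 1 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma (FDR = 0.735), and 3 without the pair. Over 14248 genes 1808 passed, 788 higher and 1020 lower on day 1, and without day 1 replicate 3 the count was 996. Without the pair 5415 genes passed between day 1 and day 0, 3460 between day 2 and day 1 and 7011 between day 3 and day 2. Fits of only the 2 days gave 4752, 2165 and 6421.

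From day 1 to day 2, presomitic markers rose further and streak genes fell. TBX6 rose to 50.6 ± 20.3 TPM (3.11 ± 0.77, adjusted p = 0.0194) and MSGN1 to 91.1 ± 16.3 (2.93 ± 0.43). HES7, an oscillating repressor of the segmentation clock, rose to 19 ± 2.88 from 0.91 ± 0.704 TPM (4.43 ± 0.94). Of 14 presomitic genes 5 rose, CDX2 by 5.28 ± 0.61, and 2 fell, among them FGF17 (-3.6 ± 0.55), (alone 7 and 3, FDR = 0.00873, up). Of 12 streak genes 8 fell (alone 8, FDR = 9.77e-10). MIXL1 fell to 14.9 ± 1.61 TPM, TBXT to 63.4 ± 12 (-2.23 ± 0.37) and EOMES to 7.98 ± 1.69 from 355 ± 111. GSC fell to 1.64 ± 0.697 from 67.9 ± 19.5 TPM and CER1 to 0.1 ± 0.0889 from 193 ± 3.52. Nodal pathway genes fell in 5 of 8 cases (alone 7, FDR = 7.03e-08), with NODAL at 0 in all 3 libraries and TDGF1 at 0.267 ± 0.275 TPM. HOX genes rose in 11 of 26 cases and HOXD13 (-3.16 ± 0.88) fell (alone 14 and 1, FDR = 1.86e-08, up). HOXB1 rose to 25.9 ± 4.74 TPM from 0.11 ± 0.191, HOXB2 to 19 ± 2.59 and HOXA3 to 2.17 ± 0.454 from 0. Somite genes rose in 5 of 16 cases and PAX7 (-5.87 ± 1.46) fell (alone 7 and 3, FDR = 9.42e-07, up). ALDH1A2, the enzyme that makes retinoic acid in the trunk, stood at 348 ± 34.7 against 4.15 ± 1.28 TPM, and TCF15 (2.61 ± 0.51) rose. MEOX1 (chromosome 12, 19431397 to 19452430) rose to 1.08 ± 0.697 TPM (2.72 ± 0.78). FOXC2 (chromosome 6, 2552141 to 2555041) stood at 1.76 ± 0.609 TPM (adjusted p = 0.0624) and SOX2 at 2.88 ± 0.411 (0.956), and neither passed. FOXC2 passed without the pair (adjusted p = 0.000175). FGF-ERK targets rose in 4 of 11 cases (alone 5, FDR = 0.000641), with the phosphatase gene DUSP6 at 365 ± 24.9 against 45.1 ± 9.18 TPM, SPRY1 (2.92 ± 0.57) and IL17RD (1.28 ± 0.36). POU5F1 fell to 136 ± 7.87 TPM (-2.17 ± 0.44) and NANOG to 1.13 ± 0.414, with 5 of 15 pluripotency genes lower in all (alone 7, FDR = 0.00049). The clock genes HES4, HES7 and DUSP6 rose and MESP2 (-4.63 ± 1.0) and DKK1 (-2.51 ± 0.65) fell, of 15 (alone 3 and 2, FDR = 0.0317, up). Of 11 Wnt targets TNFRSF19 (1.44 ± 0.22) rose and DKK1 and LGR5 (-3.4 ± 0.84) fell (alone 2 and 2, FDR = 0.632, up, median 0.22, mean -0.068). Without the pair 3 rose, with RNF43 (1.05 ± 0.31) and ZNRF3 (1.63 ± 0.23), and 3 fell (FDR = 0.713). SOX17 (-1.94 ± 0.45) and CER1 fell and FOXA1 (3.03 ± 0.35) rose among 11 endoderm genes (alone 3 and 1, FDR = 9.97e-05, down). KDR (-2.34 ± 0.56) fell among 10 lateral plate genes (alone 3, FDR = 0.00409), and 6 fell without the pair, HAND1, HAND2 and GATA4 among them. JUN (1.79 ± 0.35) and IER2 (1.17 ± 0.25) rose among 12 stress genes (alone 5, with 2 lower, FDR = 0.0119). Of 10 BMP targets 0 passed by edgeR (alone 3 lower, 4 at an unadjusted p under 0.05, 3 by DESeq2 and 2 by limma, FDR = 0.124). Without the pair 5 fell, among them MSX1, MSX2 and SMAD7, and 2 rose (FDR = 3.34e-06). Of 17 cell cycle genes 0 passed by edgeR, DESeq2 or limma, alone or at an unadjusted p under 0.05 (FDR = 0.826, median -0.013, mean 0.062). Without the pair CDK1 rose (adjusted p = 0.00314). CD5L rose to 129.6 ± 16.8 TPM, DKK4 fell (-7.46 ± 1.23) and FGF4 fell from 33.9 ± 16.5 TPM to 0. Across all genes 1053 passed, 562 higher and 491 lower on day 2. Without PSM replicate 2 the count was 526.

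From day 2 to day 3 most presomitic genes fell. MSGN1 fell from 91.1 ± 16.3 TPM to 0 in all 3 libraries, TBX6 to 1.44 ± 1.31 TPM (-5.52 ± 0.89, adjusted p = 0.000269) and HES7 to 0.157 ± 0.155 (-7.02 ± 1.15). TBXT fell to 1.95 ± 0.881 TPM and MIXL1 to 0.56 ± 0.733. Of presomitic genes 9 of 14 fell (alone 10, FDR = 4.9e-08) and of clock genes 9 of 15 (alone 10, FDR = 1.71e-09). Streak genes fell in 7 of 12 cases and CER1 (2.96 ± 0.6) rose (alone 8 and 1, FDR = 5.85e-09, down). Targets of FGF-ERK signalling fell in 9 of 11 cases (alone 10, FDR = 7.25e-10). DUSP6 fell to 0.877 ± 0.317 from 365 ± 24.9 TPM (-8.92 ± 0.89), ETV5 to 0.19 ± 0.101 and SPRY4 to 0.107 ± 0.0462. Wnt targets fell in 8 of 11 cases (alone 9, FDR = 1.29e-06), among them DKK1 (to 2.61 ± 1.8 from 146 ± 21.2 TPM), NKD1 (-4.84 ± 0.43) and AXIN2 (-2.88 ± 0.71). BMP targets rose in 3 of 10 cases (alone 4 higher and 1 lower, FDR = 0.0373), ID4 to 218 ± 22.6 from 10.5 ± 1.91 TPM, ID2 by 3.52 ± 0.65 and SMAD9 by 4.71 ± 1.32. Somite genes did not move as a block, with 2 higher and 3 lower of 16 (alone 3 and 4, FDR = 0.538, up, median 0.32 (-0.036 at the floor)). EYA1 rose to 25.3 ± 4.3 TPM (3.52 ± 0.54). FOXC1 (-1.65 ± 0.33), RIPPLY1 (-3.39 ± 1.06) and ALDH1A2 (115 ± 49.8 against 348 ± 34.7 TPM) fell. TCF15 (11.7 ± 1.14 against 15.8 ± 1.54 TPM, adjusted p = 0.325), MEOX1 (2.22 ± 0.7 against 1.08 ± 0.697, 0.384) and FOXC2 (14.1 ± 2.83 against 1.76 ± 0.609, 0.0691) did not pass. Without the pair FOXC2 rose (2.81 ± 0.44), one of 5 higher and 5 lower somite genes. HOXB1 fell to 0.303 ± 0.525 TPM. In all 7 of 26 HOX genes fell and HOXD13 (2.79 ± 0.88) and HOXA13 rose (alone 7 and 2, FDR = 7.16e-07, down). Among 7 retinoic acid genes RARB (4.39 ± 1.18) rose and STRA6 (-5.75 ± 0.54) and ALDH1A2 fell (alone 1 and 2, FDR = 0.0513, down, and 3.6e-05 without the pair). POU5F1 (to 15.3 ± 1.96 TPM, -3.38 ± 0.47), LIN28A (-1.33 ± 0.24) and LIN28B (-2.24 ± 0.19) fell. They were the 3 lower of 15 pluripotency genes (alone 3, FDR = 0.00668). NANOG (0.347 ± 0.6 TPM, adjusted p = 0.181) and SOX2 (9.3 ± 1.77, 0.501) did not pass. Without the pair SOX2 (1.39 ± 0.36), L1TD1 and SALL4 rose. Cell cycle genes fell in 10 of 17 cases (alone 14, FDR = 1.42e-06), among them the replication helicase genes MCM4 (-1.84 ± 0.2) and MCM6 (-1.42 ± 0.32) and CCNA2 (-1.41 ± 0.35). OSR1 rose to 29.2 ± 12.5 from 0.207 ± 0.196 TPM among 4 intermediate mesoderm genes (alone 1, FDR = 0.206, up, median -2.43 (-1.99 at the floor)), and 2 fell without the pair. KDR (-2.22 ± 0.56) fell among 10 lateral plate genes (alone 1, FDR = 0.0701, up). Without the pair 5 rose, HAND2, ISL1 and TBX20 among them (FDR = 0.000158). CER1 was the higher nodal gene of 8 (alone 2, FDR = 0.32, up, median -0.084 (1.8 at the floor), and 0.000158 without the pair). ATF3 (3.88 ± 0.91) and JUN rose and FOS (-2.73 ± 0.77), IER2 (-0.75 ± 0.25) and HSPH1 (-0.49 ± 0.14) fell among 12 stress genes (alone 3 and 4, FDR = 0.513, down, and 0.0192, up, without the pair). Of 2 skeletal muscle genes 0 passed by edgeR, DESeq2 or limma or at an unadjusted p under 0.05 (FDR = 0.185). GABRP reached 143 ± 21.2 TPM from 0.227 ± 0.216, CLDN1 82.4 ± 6.02 from 0.11 ± 0.191 and TF 57.9 ± 6.83 from 0.05 ± 0.0866. TAL2 and SCIN reached 14.8 ± 3.18 and 16.5 ± 0.821 TPM from 0. EVX1, PLPP4, PLA2G5 and CDX1 fell from 12 ± 3.13, 38.8 ± 7.51, 14.8 ± 1.07 and 7.69 ± 2.54 TPM to 0. In total 3374 genes passed, 1782 higher and 1592 lower on day 3. The count was 2212 without somite replicate 1.

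**Figure D4:**
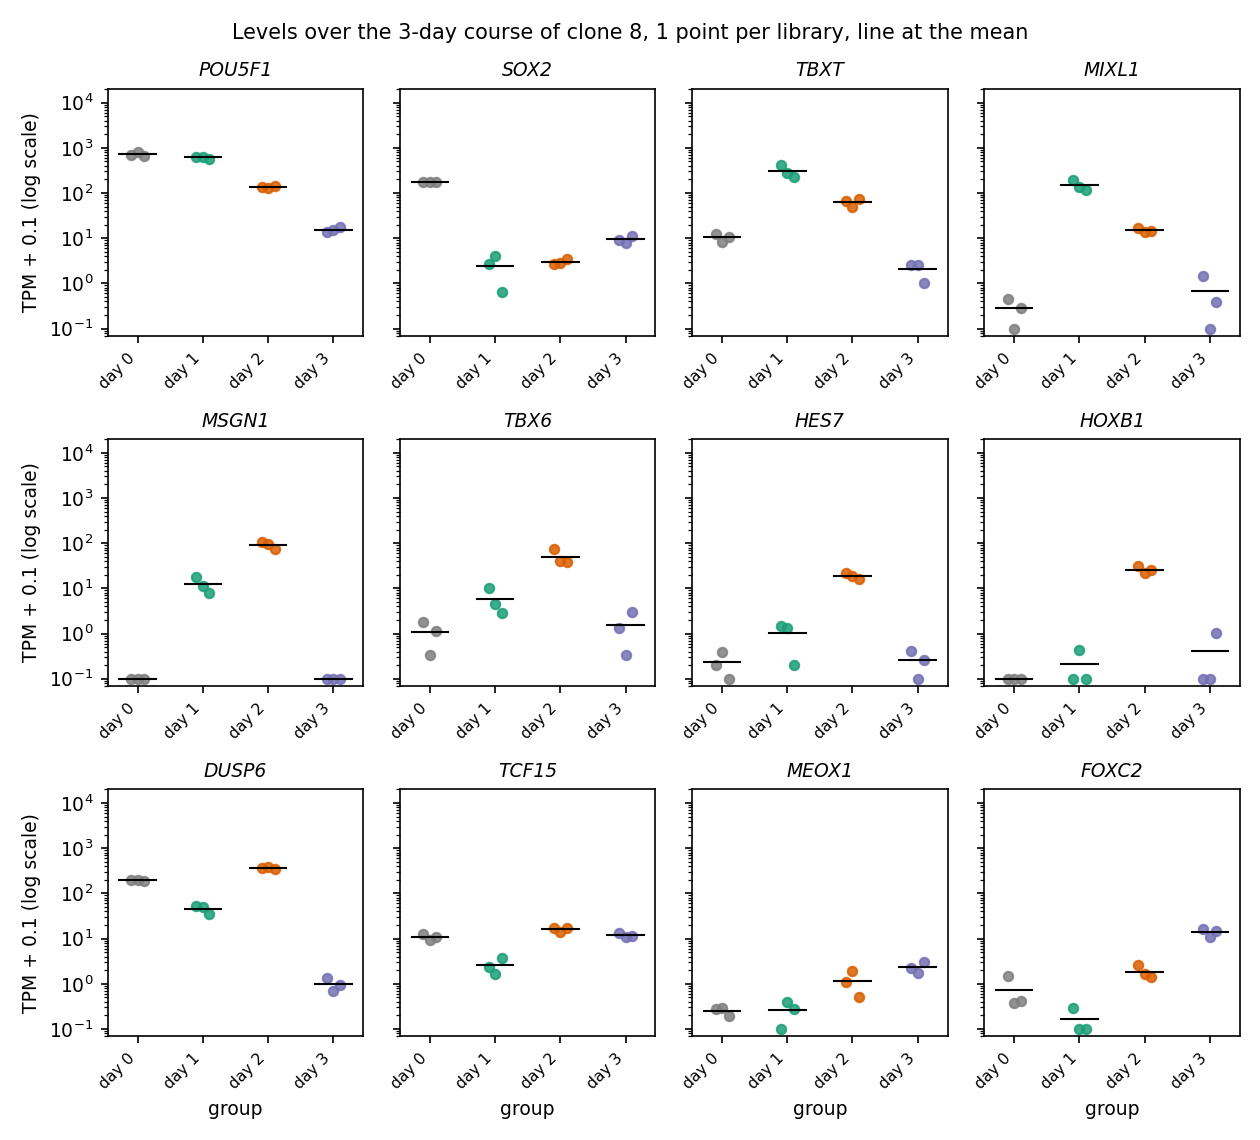
TPM + 0.1 on a log axis for 12 genes in clone 8 at day 0, day 1 (mesendoderm), day 2 (PSM) and day 3 (somite), 3 libraries each; points are libraries and lines are means. TBXT and MIXL1 peak on day 1, MSGN1, TBX6, HES7, HOXB1 and DUSP6 on day 2, and FOXC2 is highest on day 3, at 14.1 ± 2.83 TPM.

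The lineage groups asked which other programmes clone 8 entered. In the library labelled cardiomyocyte replicate 2 TNNT2, the cardiac troponin T gene, stood at 4.3 TPM and PAX6, a neural transcription factor gene, at 254. In the library labelled neural progenitor replicate 1 TNNT2 stood at 5155 and PAX6 at 0.2. Correlations across genes (Spearman, log2 CPM) of the former were 0.7167 and 0.7051 within its group and 0.9798 and 0.9731 with neural progenitor libraries 2 and 3. Those of the latter were 0.6906 and 0.7007, and 0.9871 and 0.986 with cardiomyocyte libraries 1 and 3. All groups were kept as labelled, and values without this pair (n = 2 in each of these groups), an alternative chosen after the data were seen, are given where a list's call, direction or balance of higher and lower members changed and for the main markers.

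Endothelial libraries (day 6, n = 3) against day 0 had higher levels of most endothelial genes. CDH5, the gene of VE-cadherin (chromosome 6, 27108560 to 27142145), stood at 85.7 ± 13.7 against 0.0633 ± 0.0651 TPM (10.21 ± 1.06). PECAM1 (chromosome 12, 14667643 to 14723296) stood at 284 ± 9.82 against 0.473 ± 0.0462 TPM (9.09 ± 0.74). The VEGF receptor gene KDR (chromosome 8, 41809116 to 41856379) stood at 139.6 ± 11.3 against 3.07 ± 1.14 TPM (5.54 ± 0.65, adjusted p = 1.62e-05). Of 26 endothelial genes 22 were higher (alone 23, FDR = 1.27e-08; 24 without the pair), among them EMCN at 14.4 ± 5 TPM against 0. HOX genes were higher in 24 of 26 cases (alone 24, FDR = 6.16e-13). HOXC8 stood at 50.1 ± 0.584 TPM and HOXB8 at 32.5 ± 1.93. Pluripotency genes were lower in 6 of 15 cases and higher in 2 (alone 10 and 2, FDR = 6.73e-06, down). POU5F1 stood at 1.59 ± 1.26 against 717 ± 69.9 TPM, NANOG was lower (-8.55 ± 1.0) and DPPA5 higher, at 60.2 ± 23.7 TPM against 0. DCN (6.22 ± 1.45) and PDGFRA (4.77 ± 0.72) were among 8 higher fibroblast genes of 23 (alone 10, FDR = 0.0213). TFAP2B (7.79 ± 1.83 TPM against 0), TFAP2A (20.1 ± 4.29 against 0.467 ± 0.329) and SOX10 were higher among 8 neural crest genes (alone 5, with 1 lower, FDR = 0.000151). HAND2 (8.49 ± 2.41), MEF2C and TBX5 were higher among 29 cardiomyocyte genes (alone 2, FDR = 0.615, and 0.00644 without the pair). Of 7 retinoic acid genes 4 were higher, among them ALDH1A2 (4.24 ± 0.62), RARB and CRABP2, and CYP26A1 (-2.97 ± 0.34) was lower (alone 5 and 1, FDR = 0.0814, and 4.52e-07 without the pair). Endoderm genes gave 3 lower, among them CER1 (-6.72 ± 0.44), and SOX7 higher of 11 (alone 3 and 1, FDR = 0.000477, down). Stress genes were lower in 4 of 12 cases (alone 4, FDR = 0.000446) and cell cycle genes in 3 of 17 (alone 3, FDR = 0.0213). Single lower members were PFKP of 13 glycolysis genes (alone 1, FDR = 0.676; 5 higher and 1 lower without the pair), OTX2 of 15 neural progenitor genes (alone 1, FDR = 0.875; then 7 and 4) and PTPRC of 4 blood genes (alone 1, FDR = 0.205). RGS5 and PDGFRB were higher among 10 smooth muscle genes (alone 2, FDR = 0.441), and without the pair 2 were lower too (FDR = 0.102, down). By edgeR 0 of 12 neuron genes passed, also alone, with 3 at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma (FDR = 0.635, and 8.26e-06, down, without the pair). Of 2 skeletal muscle genes 0 passed by any of these (FDR = 0.566). As labelled 2752 genes passed, 1646 higher and 1106 lower, and without the pair 6532, 3519 and 3013. Leaving out day 0 replicate 3 gave 1789, and a fit of only these groups 7704.

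In the cardiomyocyte group (day 9, n = 3) against day 0, genes of the contractile apparatus were higher with a spread nearly as wide as the mean, and the library labelled replicate 2 was low in them. TNNT2 (chromosome 10, 23749528 to 23759696) stood at 2931 ± 2535 against 1.9 ± 0.555 TPM (10.99 ± 2.71) as labelled and at 4394 ± 20.2 (11.57 ± 0.32) without the pair. MYL4, an atrial light chain gene, stood at 3030.4 ± 2639.8 against 0.853 ± 0.755 TPM and at 4545 ± 423 without the pair. The transcription factor gene NKX2-5 (chromosome 16, 51086014 to 51089165) stood at 23.5 ± 20.8 against 0.4 ± 0.377 TPM and at 35.3 ± 5.93. The calcium handling gene PLN stood at 129.6 ± 112 TPM as labelled, at 193 ± 27.2 without the pair and at 0 on day 0. Of 29 cardiomyocyte genes 28 were higher (alone 29, FDR = 0.0159), and 29 without the pair (FDR = 4.29e-13). Of 23 fibroblast genes 14 were higher and 1 lower (alone 15 and 1, FDR = 0.0475), and 20 were higher without the pair. Without the pair POSTN (10.96 ± 0.34) and ACTA2 (7.61 ± 0.29) were higher. Smooth muscle genes were higher in 5 of 10 cases (alone 7, FDR = 0.0317), and in 9 without the pair. As labelled 6 of 12 neuron genes were higher (alone 8, FDR = 0.364), and PAX6 stood at 84.9 ± 147 TPM (7.72 ± 2.32). Without the pair 6 were lower and 1 higher (FDR = 4.43e-08, down), and PAX6 had a log2 fold change of -0.595 (adjusted p = 0.554). Neural progenitor genes gave 6 higher and 1 lower of 15 (alone 6 and 1, FDR = 0.985, down, median 3.35), and 10 lower without the pair (FDR = 7.61e-08). POU5F1 (0.443 ± 0.431 against 717 ± 69.9 TPM) and NANOG (-8.28 ± 0.99) were lower with 11 of 15 pluripotency genes (alone 11, FDR = 9.86e-10). Cell cycle genes were lower in 10 of 17 cases (alone 10, FDR = 7.12e-08). LDHA (3.16 ± 0.62) was among 3 higher glycolysis genes of 13, with 1 lower (alone 3 higher, FDR = 0.0227). Endoderm genes gave 2 higher and 7 lower of 11 (alone 2 and 7, FDR = 6.47e-08, down), and stress genes 1 and 5 of 12 (alone 1 and 5, FDR = 4.42e-05, down). HOX genes gave 3 and 2 of 26 (alone 3 and 1, FDR = 0.013, up), and retinoic acid genes 1 and 3 of 7 (alone 1 and 3, FDR = 1.64e-05). Endothelial genes gave 5 and 3 of 26 (alone 5 and 3, FDR = 0.278, down, median 0.22 (0.33 at the floor); 0.213, up, without the pair), and neural crest genes 3 and 2 of 8 (alone 3 and 2, FDR = 0.59, down, median 2.94 (2.5 at the floor); 1 and 2, 0.00582, without the pair). PTPRC was lower among 4 blood genes (FDR = 0.118, and 0.00491 without the pair) and CKM higher of 2 skeletal muscle genes (FDR = 0.0468). As labelled 5940 genes passed, 3262 higher and 2678 lower, relative to a median of all genes of 0.20, and without the pair 8934, 4388 and 4546. A fit of only these groups gave 3764.

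**Figure D5:**
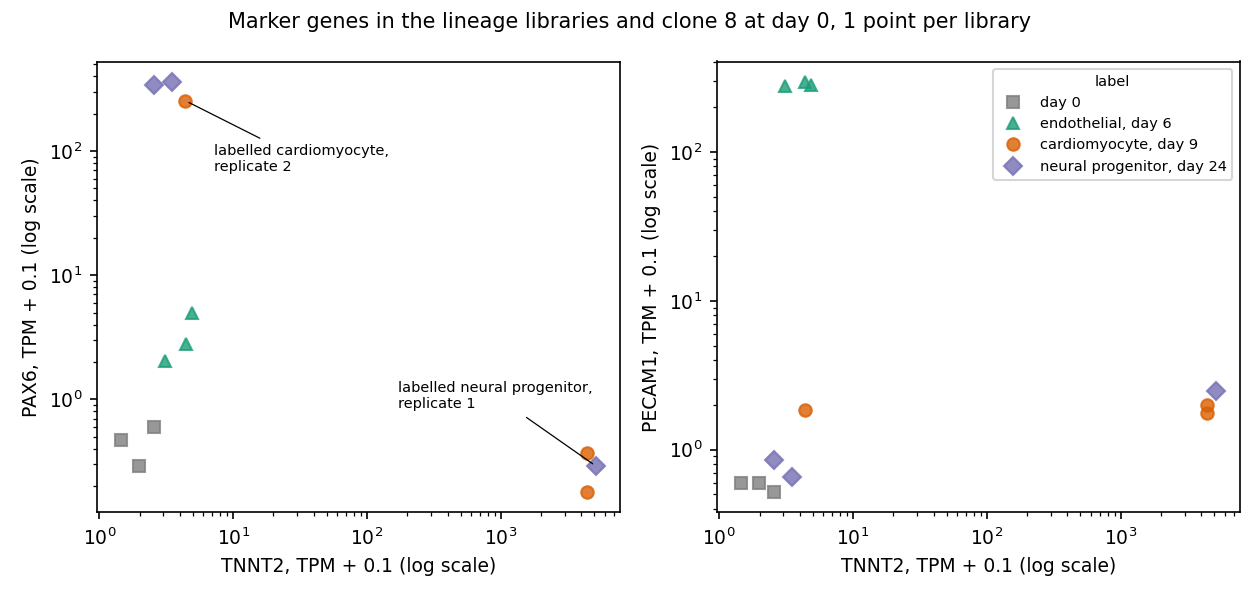
TPM + 0.1 on log axes of PAX6 (left) and PECAM1 (right) against TNNT2 in clone 8 at day 0 and in the endothelial, cardiomyocyte and neural progenitor groups, 3 libraries each, 1 point per library, coloured by label. The library labelled cardiomyocyte replicate 2 lies with the neural progenitor libraries and the library labelled neural progenitor replicate 1 with the cardiomyocyte libraries.

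In the neural progenitor group (day 24, n = 3) against day 0, PAX6 (chromosome 2, 28971565 to 29001149) stood at 233 ± 202 against 0.353 ± 0.156 TPM as labelled (8.99 ± 2.41) and at 349 ± 14.4 without the pair (9.58 ± 0.34). DCX, a microtubule-associated protein of young neurons, stood at 200.3 ± 173 TPM and at 300.2 ± 10.5 without the pair. The intermediate filament gene NES (chromosome 4, 93412660 to 93421899) stood at 362 ± 252 against 63.1 ± 15.9 TPM (2.22 ± 0.55). SOX1 (chromosome 11, 77985771 to 77989383; adjusted p = 0.0502) did not pass as labelled and did without the pair (5.08 ± 0.47). Of 15 neural progenitor genes 7 were higher and OTX2 (-3.59 ± 0.79) lower (alone 11 and 1, FDR = 0.285), and without the pair 13 and 1 (FDR = 1.37e-11). Neuron genes went from 9 of 12 (alone 10, FDR = 0.0727) to 12 (FDR = 2.51e-15). As labelled 26 of 29 cardiomyocyte genes were higher (alone 27, FDR = 0.0793), and without the pair 10 were higher and 4 lower (FDR = 0.022). POU5F1 (0.98 ± 1.33 against 717 ± 69.9 TPM) was lower with 11 of 15 pluripotency genes (alone 11, FDR = 7.8e-09). So were 11 of 17 cell cycle genes (alone 12, FDR = 1.07e-08). Fibroblast genes gave 12 higher and 1 lower of 23 (alone 12 and 1, FDR = 0.195; 6 and 10, 0.221, down, without the pair), and HOX genes 5 and 1 of 26 (alone 5 and 0, FDR = 0.00265). Endothelial genes gave 3 and 3 of 26 (alone 1 and 3, FDR = 0.0237; 2 and 6 without the pair), neural crest genes 3 and 2 of 8 (alone 4 and 2, FDR = 0.575) and stress genes 2 and 5 of 12 (alone 2 and 6, FDR = 1.71e-05). Glycolysis genes were higher in 5 of 13 cases (FDR = 0.0157), smooth muscle genes in 3 of 10 (FDR = 0.0924, and 0.000196, down, without the pair) and skeletal muscle genes in 1 of 2 (FDR = 0.0417, and 0.0747 without the pair), alone 5, 3 and 2. Endoderm genes were lower in 7 of 11 cases (FDR = 2.37e-08), retinoic acid genes in 3 of 7 (FDR = 4.35e-06) and blood genes in 1 of 4 (FDR = 0.352; 1 higher and 1 lower, 0.538, up, without the pair), alone 7, 3 and 1. As labelled 6087 genes passed, 3385 higher and 2702 lower (median of all genes 0.20), and without the pair 9236, 4633 and 4603. A fit of only these groups gave 3476.

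To find what set each lineage apart, each was also compared with the mean of the other two. In the endothelial group CDH5, PECAM1 (7.28 ± 0.5) and KDR (6.56 ± 0.51) were higher, with 24 of 26 endothelial genes (alone 25, FDR = 1.15e-11). PAX9 (20.8 ± 1.94 against 0.0133 ± 0.0327 TPM) was among the most enriched. HOX genes were higher in 24 of 26 cases (alone 24, FDR = 1.43e-12), retinoic acid genes in 4 of 7 (alone 4, FDR = 3.62e-10) and pluripotency genes in 7 of 15 (alone 7, FDR = 8.29e-08). Neural crest genes were higher in 4 of 8 cases (alone 4, FDR = 5.85e-06), cell cycle genes in 9 of 17 (alone 10, FDR = 3.61e-08) and endoderm genes in 7 of 11, with GATA4 lower (alone 8 and 1, FDR = 1.02e-07, up). TNNT2 (-9.52 ± 2.51) was lower with 24 of 29 cardiomyocyte genes (alone 26, FDR = 0.0515, and 1.85e-08 without the pair). Neuron genes were lower in 9 of 12 cases (alone 12, FDR = 0.0821, and 1.84e-09 without the pair), and PAX6 (-5.21 ± 1.9) was lower with 4 of 15 neural progenitor genes (alone 1, FDR = 0.579; 4 higher and 4 lower without the pair). Smooth muscle genes were lower in 4 of 10 cases (alone 6, FDR = 0.282, and 3.91e-06 without the pair), glycolysis genes in 4 of 13 (alone 6, FDR = 0.0205) and skeletal muscle genes in 2 of 2 (FDR = 0.00418). Fibroblast genes split 3 and 3 of 23 (alone 3 and 3, FDR = 0.42, up, median -0.14 (-0.17 at the floor); 14 and 5, 4.47e-05, without the pair) and stress genes 2 and 2 of 12 (FDR = 0.0639; 3 and 2, 0.0363, without the pair). Of 4 blood genes 0 passed by edgeR, DESeq2 or limma or at an unadjusted p under 0.05 (FDR = 0.959), and 1 without the pair. In all 4737 genes passed, 2481 higher and 2256 lower, 7162 without the pair, 3146 without endothelial replicate 3 and 1832 in a fit of only these groups.

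The cardiomyocyte group as labelled was set apart by 930 genes (402 higher, 528 lower), by 8729 without the pair, 298 without cardiomyocyte replicate 3 and 14 in a fit of only these groups. MYL4 was higher by 6.26 ± 1.73 (adjusted p = 0.0408). TNNT2 (5.37 ± 1.59, 0.0526) and NKX2-5 (3.06 ± 1.28, 0.156) did not pass as labelled, and were higher by 10.89 ± 0.27 and 7.0 ± 0.61 without the pair. Cardiomyocyte genes were higher in 10 of 29 cases (alone 26, FDR = 0.0228), and in 29 without the pair (FDR = 1.61e-11). KDR (-3.39 ± 0.59) and PECAM1 (-3.34 ± 0.57) were lower with 6 of 26 endothelial genes (alone 9, FDR = 0.000497). HOX genes were lower in 8 of 26 cases (alone 13, FDR = 4.09e-06) and cell cycle genes in 5 of 17 (alone 5, FDR = 0.00288). Without the pair cell cycle genes split 7 higher and 7 lower (FDR = 0.523), CDK1 at 1.9 ± 0.19 and MKI67 at -2.15 ± 0.39. Retinoic acid genes were lower in 3 of 7 cases (alone 3, FDR = 0.0103; 2 higher and 2 lower, 0.826, without the pair) and pluripotency genes in 2 of 15 (alone 5, with 1 higher, FDR = 0.00189). By edgeR 0 of 15 neural progenitor genes passed, and 0 by DESeq2, limma or an unadjusted p under 0.05 (FDR = 0.631, down, median 0.4). Without the pair 15 were lower (FDR = 6.24e-11). By edgeR 0 of 12 neuron genes passed (alone 1, unadjusted 3, DESeq2 2, limma 0, FDR = 0.759), and without the pair 10 were lower (FDR = 2.36e-11). Of 23 fibroblast genes 0 passed (unadjusted 4, DESeq2 3, limma 0, FDR = 0.751), and without the pair 17 were higher (FDR = 4.85e-09). The endoderm list moved down in fry (FDR = 0.0438) with 0 of 11 past edgeR's test (alone 1 higher and 3 lower, unadjusted 5, DESeq2 2, limma 3). Without the pair it moved up (FDR = 0.00195). The neural crest list moved down as labelled (FDR = 0.00248) and without the pair (FDR = 0.000531), as labelled with 0 of 8 (alone 2 lower, then 2, 0 and 4 in the same order). Smooth muscle (1 of 10 higher, alone 2, FDR = 0.203, and 2.36e-11 without the pair) and glycolysis (1 of 13, alone 1, FDR = 0.234, and 0.000264 without the pair, with 7 higher, LDHA by 2.47 ± 0.2, and 3 lower) did not pass in fry as labelled. Nor did stress genes (1 of 12 lower, alone 1, FDR = 0.92, down, median 0.13, and 4.15e-05, up, without the pair). Of skeletal muscle and blood genes 0 passed by any tool (FDR = 0.111 and 0.816). Without the pair ACTA1 and CKM (2.3 ± 0.81) were higher (FDR = 0.0614) and MYB (-5.06 ± 0.9) lower (FDR = 0.00912).

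The neural progenitor group as labelled was set apart by 1130 genes (562 higher, 568 lower), by 9150 without the pair, 316 without neural progenitor replicate 3 and 26 in a fit of only these groups. SIX3, an anterior neural factor gene, was higher as labelled (4.84 ± 1.33). PAX6 (3.56 ± 1.39, adjusted p = 0.122), SOX1 (0.295) and NES (0.183) did not pass. Without the pair they were higher, PAX6 by 8.34 ± 0.27, SOX1 by 5.41 ± 0.44 and NES by 1.93 ± 0.21. Neural progenitor genes were higher in 1 of 15 cases (alone 1, FDR = 0.194), and in 15 without the pair (FDR = 1.54e-11). Neuron genes were higher in 4 of 12 (alone 12, FDR = 0.0306) and 12 (FDR = 1.68e-13). HCN4 (2.75 ± 0.45), a pacemaker channel gene, was the higher cardiomyocyte gene of 29 (alone 1, FDR = 0.558), and without the pair 22 were lower (FDR = 8.11e-08). CDH5 (0 against 42.9 ± 47.6 TPM) was lower with 11 of 26 endothelial genes (alone 14, FDR = 3.46e-06). Cell cycle genes were lower in 8 of 17 cases (alone 11, FDR = 4.32e-05) and HOX genes in 4 of 26 (alone 8, FDR = 8.75e-05). Retinoic acid genes were lower in 4 of 7 cases (alone 4, FDR = 0.000215), pluripotency genes in 3 of 15 (alone 4, FDR = 0.0277, and 0.0336, up, without the pair) and endoderm genes in 2 of 11 (alone 2, FDR = 0.0113). By edgeR 0 of 23 fibroblast genes passed (unadjusted 4, DESeq2 3, limma 2, FDR = 0.385, and 1.33e-08, down, without the pair). Of 10 smooth muscle genes 0 passed (2, 0 and 0 in the same order, FDR = 0.757, and 1.33e-08, down, without the pair). Of 8 neural crest genes 0 passed by edgeR (2, 0 and 2, FDR = 0.545; 4 higher and 2 lower without the pair), and of 2 skeletal muscle genes 0 (alone 2; 2, 0 and 0, FDR = 0.0648; 1 without the pair). GPI was the higher glycolysis gene (FDR = 0.173; 3 higher and 5 lower without the pair), JUN was higher and IER2 lower among stress genes (FDR = 0.247; 2 and 7, 5.02e-05, without the pair), and of 4 blood genes 0 passed by any tool (FDR = 0.723; MYB higher, 0.00564, without the pair).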

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

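Tests of the pair, chromosome Y and, for chromosome 17, a few genes and an extra copy were chosen after the result was seen. So were the stretch of Y and chromosome 17. The scaling test of chromosome 17 and the counts over other splits of the libraries were written before.

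The libraries labelled cardiomyocyte replicate 2 and neural progenitor replicate 1 each sat with the other group. Mixed RNA of both cell kinds is argued against. The median level of genes abundant in one kind and low in the other was 0.003265 of that kind's level in the former library (26 genes, 24 under 0.1) and 0.001499 in the latter (25 genes, 24 under 0.1). An exchange of the labels of these libraries needs a partner out of place in each group, and 2 libraries were. A candidate explanation is therefore that the labels were exchanged at some step, while differentiation that went another way in both cultures was not tested and stays open.

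Genes of chromosome Y between 9155794 and 10444524 were counted in clones 1 to 3 and barely in fibroblasts or clone 8. Their summed TPM was 3493 to 12091 in the 11 clone libraries, at most 2.69 in fibroblasts, 0.06 to 0.28 on day 0 and 12.9, 5.23 and 8.86 in the day 3 libraries. LOC110257905 made up most of it in the clones. Depth is argued against, since the shallowest of the 25 other libraries would hold 5260 such counts at the level of the clones and held 1. Use in pluripotent cells alone is argued against, since day 0 of clone 8, also pluripotent, had 0.002792% of the clones' level. A reference without chromosome Y is argued against, since each of the 25 libraries held 1 to 99 counts of these genes. All 8 genes were below the clones in each of the other libraries, so fibroblasts and clone 8 may come from other animals than clones 1 to 3 or may have lost Y. These cannot be told apart, because the labels name no animal.

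Genes of chromosome 17 had a median log2 difference of 0.53 between clone 3 and the mean of clones 1 and 2, against -0.037 to 0.062 for the other 18 chromosomes. A few strong genes are argued against by the 89.21% of 445 genes that were higher, and scaling by a gap to the other genes of 0.52 under TMM, 0.52 under RLE and 0.4028 in TPM. An extra copy of the whole chromosome in most cells of clone 3 would put every stretch near 0.58. The 7 stretches with 10 or more genes had medians of 0.4222 to 0.59, and 27% of the chromosome's genes passed as higher against 1.75% of other genes. An extra copy is a candidate explanation, as a hypothesis found and tested on the same data, and no other biological difference of the clones was tested.

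In groups of 4, 31 of 316 sets of values had a library past Dixon's 95% critical value (15.8 by chance without ties). The value is the gap to the nearest library over the whole range. With the others tied it is 1, so 31 cannot be compared with 15.8. In fibroblasts it was 1 for CER1, DKK1, FOXA1, GRHL2, RBM46, SOX17, SOX2 and TBXT, with 1 library above 0 and the others at 0, 0.8913 for LIN28B, 0.9423 for SLC3A1, 0.8333 for SOX11 and 0.8571 for TCEAL2. In clone 2 it was 0.9464 for CHI3L1, 0.8957 for DKK1, 0.8571 for FAM83F, 0.9615 for FOXA1, 0.8473 for KRT79, and 1 for PEG3 and ZBED2. Clone 3 replicate 1 accounted for 6 of the 12 sets in clone 3. There the value was 0.9433 for the mean of the cell cycle list, 0.8372 for BIRC5 (222 against 374 to 403 TPM), 0.9442 for PCNA (333 against 492 to 502 TPM) and 0.9602 for LEFTY2 (50.3 against 19.4 to 20.7 TPM). The others in clone 3 were 1 for ASPN, 0.9036 for DCN, 0.8326 for DOK5, 0.8889 for FAM83F, 0.8545 for FOS, 0.8467 for NPM2, 0.8333 for SHISA2 and 0.8646 for TCEAL2.

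Genes called in opposite directions against fibroblasts in a pair of clones numbered 19 for clones 1 and 2, 15 for clones 1 and 3 and 20 for clones 2 and 3. All of these also passed the test of one clone against the other. They include KCNT2 and GABRA3 for the first pair, PEG3 and NDN for the second pair, and KCNT2, SDK1 and FOS for the last.

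The real grouping was set against other splits of the same libraries into groups of the same sizes. For clones against fibroblasts, of 100 splits 1, the real one, gave as many as 10930 genes, and the highest other gave 5216. The same held, with 1 of 35 splits each, for clone 1 (10186, highest other 6663), clone 2 (10246 and 0) and clone 3 (10355 and 0) against fibroblasts. It also held for clone 1 against clone 2 (1365 and 4), clone 1 against clone 3 (982 and 289) and clone 2 against clone 3 (618 and 0). The split with 6663 genes set 3 fibroblast libraries against clone 1 with fibroblast replicate 3, so it kept part of the real structure. Against the other lineages, chance cannot be excluded either for endothelial (4737 genes, 4 of 100 splits, highest other 9836), a share too near 0.05. Nor can it for cardiomyocyte (930, 14 of 100, 9836) or neural progenitor (1130, 9 of 100, 8314). Splits with several times the real count point to a structure of the samples, and the highest placed cardiomyocyte replicate 2 with neural progenitor replicates 2 and 3. Groups of 3 against 3 have 10 splits, too few for a share under 0.05. The real split and the highest other gave 2752 and 0 genes for endothelial against day 0, 5940 and 0 for cardiomyocyte and 6087 and 0 for neural progenitor. From day 0 to 1, 1 to 2 and 2 to 3 they gave 1808 and 0, 1053 and 0, and 3374 and 0.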

How the results depend on the processing

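Some fits were chosen after the data were seen, as given above. For the values that moved the cause was not tested, except where fewer genes or samples by construction show it.

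No named gene turned direction under RLE scaling, DESeq2, limma, no filter, the block, all libraries in 1 fit or only the groups compared. Over all genes the naming rule gives, 799 of 883 results kept call and direction with DESeq2, 877 with RLE and 856 with no filter. Limma kept 759 on log2(TPM + 1) and 753 on log2(TPM + 0.1), all libraries in 1 fit 782 and the block 826. With only the groups compared 610 of 796 did. Without the pair 434 of 681 did, 177 newly passed, 20 no longer did and 50 reversed. Of 6696 results with 1 library left out 29 reversed. PAX6 in cardiomyocyte against day 0 turned to -0.595 without the pair, and ran from -0.5891 without cardiomyocyte replicate 2 to 8.242.

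Fry's direction turned in 9 lists that passed without the pair, with these medians. For the endoderm, pluripotency and day 3 stress results the direction was up and the fitted median below 0. In cardiomyocyte against day 0 it was -1.8 for neuron genes, and in neural progenitor against day 0 -0.7829 for smooth muscle genes. In cardiomyocyte against the other lineages it was -1.335 for endoderm, -5.285 for neuron and 0.3588 for stress genes. In neural progenitor against the others it was -0.2119 for pluripotency (0.49 at the floor of 3 counts), -3.196 for smooth muscle and -3.705 for cardiomyocyte genes. From day 2 to day 3 it was -0.3815 for stress genes. With only the groups compared it turned for neural crest genes in neural progenitor against day 0 (-4.2) and genes of stress and immediate early response, day 3 versus day 2 (up, -0.2217).

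Counts of genes over 1.5 times apart from those reported were as follows. DESeq2 gave 2247 for clone 1 against clone 2, 1877 for clone 1 against clone 3, 1243 for clone 2 against clone 3, 1816 for cardiomyocyte and 1936 for neural progenitor against the other lineages, and 1695 for day 2 against day 1. A fold change of at least 2 left 754, 563, 280, 548 and 693 for the first 5 of these. All libraries in 1 fit gave 909, 620, 347, 1402 and 1717. Limma on log2(TPM + 1) gave 1052 for clone 2 against clone 3 and 1686 for cardiomyocyte against the others, 1041 and 1641 with no filter, and 1517 for the latter on log2(TPM + 0.1). With only the groups compared, clone 2 against clone 3 gave 2561. Endothelial, cardiomyocyte and neural progenitor gave 7704, 3764 and 3476 against day 0 and 1832, 14 and 26 against the others. Day 1, day 2 and day 3 gave 4752, 2165 and 6421 against the day before. Without the pair the lineages gave 6532, 8934 and 9236 against day 0 and 7162, 8729 and 9150 against the others, and the days 5415, 3460 and 7011. Summing each clone to 1 library gave 9364 against fibroblasts, within 1.5 times.

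Leaving out 1 library at a time gave 10371 to 11196 genes for clones against fibroblasts, 9730 to 10142 for clone 1, 9710 to 10144 for clone 2 and 9804 to 10295 for clone 3, all within 1.5 times. Clone 1 against clone 2 ran from 643 to 1757, with 853 without clone 1 replicate 2 and 852, 798, 643 and 797 without clone 2 replicates 1 to 4. Clone 1 against clone 3 ran from 435 to 1332, with 457, 435 and 553 without clone 3 replicates 2, 3 and 4. Clone 2 against clone 3 ran from 330 to 549, with 388, 401 and 330 without clone 2 replicates 1 to 3 and 357 and 351 without clone 3 replicates 2 and 3. Endothelial against day 0 ran from 1789 to 1970, with 1806, 1790 and 1789 without day 0 replicates 1 to 3. Cardiomyocyte ran from 4477 to 6885 and neural progenitor from 4663 to 7519. Endothelial against the others ran from 3146, without endothelial replicate 3, to 6076. Cardiomyocyte against the others ran from 298 to 4500, with 489 and 469 without endothelial replicates 2 and 3, 451, 4500 and 298 without cardiomyocyte replicates 1 to 3, and 3988 and 568 without neural progenitor replicates 1 and 2. Neural progenitor against the others ran from 316 to 6152, with 566 and 604 without endothelial replicates 2 and 3, 626, 4510 and 673 without cardiomyocyte replicates 1 to 3, and 6152, 322 and 316 without neural progenitor replicates 1 to 3. Day 1 against day 0 ran from 996 to 1595, with 1040, 1076 and 1107 without day 0 replicates 1 to 3 and 1000 and 996 without day 1 replicates 2 and 3. Day 2 against day 1 ran from 526 to 693, with 693, 627 and 607 without day 1 replicates 1 to 3 and 630, 526 and 680 without day 2 replicates 1 to 3. Day 3 against day 2 ran from 2212, without day 3 replicate 1, to 2727, with 2218 without day 2 replicate 3.

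No comparison had all correlations of same-numbered libraries over 0.1, so no pairing was assumed. In endothelial against day 0 all 3 correlated best with their own number (r 0.0156 to 0.0921). So did 2 of 3 for day 1 against day 0 (0.0741 to 0.2423) and day 2 against day 1 (0.088 to 0.3619). These are hints from the data, not the design. With the replicate number as a block 10648 genes passed for clones against fibroblasts, 9696, 9975 and 10055 for clones 1 to 3, 953, 724 and 472 between clones, 2712, 5541 and 5728 for the lineages against day 0, 4431, 835 and 1058 against the others and 1761, 1006 and 3281 along the days. All lie within 1.5 times, and 173 of 180 list results kept their call. Calls were gained for endoderm in clone 1 against clone 3 (FDR = 0.033), and for retinoic acid genes in endothelial against day 0 (0.046) and day 3 against day 2 (0.0204). They were lost for imprinted genes in clone 2 against clone 3 (0.0727), fibroblast and skeletal muscle genes in cardiomyocyte against day 0 (0.0513 and 0.0581) and skeletal muscle genes in neural progenitor against day 0 (0.0565). In clone 8, with fewer counts, edgeR recovered 4% of simulated 2-fold changes between day 0 and day 1 and 22% for endothelial against the others. The simulated spread of clone 8 included the pair. Depth and spread were not tested apart.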

Other observations

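These lists had not been tied to the comparisons concerned beforehand, and the genes named were chosen after their values were seen. HOX genes, which set position along the body axis, were lower in the clones than in fibroblasts in 26 of 28 cases (adjusted over the list alone 26, FDR = 4.19e-12, median -8.33 (-7.39 at the floor)), as with HOXA10 (-7.52 ± 0.84) and HOXB7 (-6.87 ± 0.78). Smooth muscle genes were lower in 9 of 10 cases (alone 9, FDR = 3.65e-10), as with MYH11 (-10.17 ± 0.26) and TAGLN (-4.06 ± 0.14). Endoderm genes were higher in 10 of 11 cases and lower in 1 (alone 10 and 1, FDR = 7.45e-10), as with SOX17 (10.43 ± 0.48).

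From day 2 to day 3, glycolysis genes fell in 12 of 13 cases (alone 12, FDR = 4.01e-07, median -1.53), among them LDHA (-3.47 ± 0.63), HK2 (-2.91 ± 0.94) and ENO1 (-2.72 ± 0.35). Epithelial genes rose in 9 of 16 cases (alone 11, FDR = 4.15e-05, median 1.87), among them CDH1 (2.97 ± 0.52), RAB25 (2.88 ± 0.52) and GRHL2 (1.63 ± 0.4). Imprinted genes rose in 3 of 13 cases (alone 3, FDR = 0.00252), namely IGF2 (6.33 ± 1.54), CDKN1C (2.7 ± 0.43) and IGF2R (1.02 ± 0.32).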
